A study of Ipomoea batatas with 6 samples.

How the data were processed

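Leaf RNA was profiled by RNA sequencing in 6 libraries of sweet potato (Ipomoea batatas, variety Lizixiang), 2 from each of 3 groups. The groups were untransformed plants (WT), plants overexpressing IbBBX24 (IbBBX24-OE) and plants carrying an RNAi construct against IbBBX24 (IbBBX24-RNAi). Per the labels' protocols, plants grew for 1 month in a greenhouse with 16 h of light and 8 h of darkness at 28 °C, were inoculated with spores and were sampled at 1 day post inoculation. Total RNA came from leaves by the TRIzol method, and Illumina libraries were sequenced from both ends. The species of the spores is not given in the sources used here. The submitters describe the 2 libraries of a group as independent biological replicates.

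The deposited table holds FPKM values (fragments per kilobase of transcript and of counted fragments), which the authors calculated for 67830 genes per library. Reads were aligned with HISAT2 2.0.4, per the submitters' processing notes. The counting tool, the use of strand in counting and the name of the genome build are not given in the sources used here. The deposited annotation gives scaffold coordinates for 55452 of these genes, and the other 12378 loci have an identifier but no coordinates in the annotation used here. Its coordinates are printed as the file gives them, counted from 1. Exon and coding lines in the annotation have the same coordinates, so untranslated regions were not told apart.

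The files do not pair identifiers with gene names. A reference gene table of another assembly (IBA_r1.0), with 175826 genes, matched 0 identifiers, so no gene was named and IbBBX24 itself is not analysed here. The group labels were therefore not checked against the targeted gene. The lists fixed by gene name before the data were examined (jasmonate, salicylate and ethylene pathways, pathogenesis-related proteins, WRKY factors, phenylpropanoids, flavonoids, reactive oxygen enzymes, receptors, photosynthesis, B-box family, light signalling, heat shock, cell wall, storage root, dividing cells, RNA quality and markers of other tissues) have no result for the same reason. The lists by gene structure fixed with them were tested instead. These were single-exon genes, genes with 10 or more exons, the 10% shortest and the 10% longest genes by model length, loci without a model, and neighbouring genes that changed together.

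Depth was recovered from the values. FPKM times the mean transcript length and a library total gave whole reads, within 0.01, for 99.99% of the 50720 annotated genes with a value above 0. The library totals were 15187042 to 18859295 counted fragments. In those totals, 3 reads on a model of 1 kb correspond to 0.159 to 0.198 FPKM. These floors and the intervals on read ratios cover counting error only, since reads from amplified libraries are not independent molecules. Lengths of loci without a model were inferred as the shortest that made their values whole.

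Replicates were compared before averaging. A chi-square test of the recovered reads gave 4.28 per degree of freedom in WT, 2.36 in IbBBX24-OE and 2.58 in IbBBX24-RNAi, so no pair was 1 library under 2 names.

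Genes with an FPKM of at least 1 in at least 2 libraries were tested, which kept 50196 genes, 41249 of them annotated. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a mean-variance trend. All 6 libraries shared 1 estimate of the spread, with 3 residual and 4.90 prior degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Where a group had 0 reads, the fold was bounded against a floor of 3 reads over both libraries of the group. Where a group had 1 to 3 reads, the ratio of reads per counted fragment is given with an exact binomial 95% interval. Gene lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation. Neighbouring genes were tested by 1000 shuffles of the calls. Overlap of the comparisons that share the WT libraries was set beside 100 simulated data sets with no change. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for the rest.

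Named genes followed a rule fixed before the data were examined. Because no names could be had, these were the 2 genes that rose most and the 2 that fell most on the log2(FPKM + 1) scale in each comparison, among genes past the threshold whose groups did not overlap. The fit was tested on simulated data for 50196 genes. In the simulated OE vs WT comparison, 14.9% of 1.5-fold, 64.2% of 2-fold and 100% of 4-fold changes were recovered. In the simulated RNAi vs WT comparison these shares were 2.99%, 58.2% and 100%. Each fold was planted in only 66 or 67 genes, with the same spread set for all genes. Far fewer genes changed than passed in the data, which makes the adjusted threshold stricter. The shares are therefore not the power of the comparisons reported here. Alternatives covered the pseudocount, the filter, scaling, the groups in the fit, the trend, a minimum fold, a replicate block and each library left out. The read-based limma voom test, a correction for model length, the omission of genes with a close model, and quantile normalization of the overlap were chosen after seeing the data.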

Results

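Transcript levels were measured in leaves of wild-type sweet potato and of plants labelled as overexpressing or silencing IbBBX24, a member of the B-box zinc finger family, 1 day after inoculation with spores. Each of the 3 groups had 2 libraries. IbBBX24 itself is not analysed here, because the files do not pair identifiers with names, so the labels were not checked against it. Counted fragments numbered 18532488 and 18859295 in WT, 17055764 and 15187042 in IbBBX24-OE, and 16822844 and 17450997 in IbBBX24-RNAi. The comparisons asked which transcripts differed when IbBBX24 was raised, when it was lowered, and between the transgenic lines. Values are group means of FPKM with the SD over n = 2 libraries.

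Fewer genes were detected in the RNAi leaves. An FPKM of at least 1 was reached by 47067 and 47064 genes in the WT libraries, 45197 and 45323 in OE, and 42708 and 42973 in RNAi. The 10 genes with the most signal in a library held 10.1% ± 0.015 of the FPKM sum in RNAi, against 7.02% ± 0.012 in WT and 7.16% ± 0.058 in OE (SD, n = 2 each). Across genes, which are not independent replicates, log2 values of libraries of a group correlated at 0.984 to 0.987. The correlation was 0.932 to 0.934 between WT and OE, 0.800 to 0.812 between WT and RNAi, and 0.779 to 0.788 between OE and RNAi. The first principal component held 77.3% of the variance and set RNAi apart, and the next held 16.4% and separated WT from OE. For such library summaries, an exact two-sided permutation test of 2 libraries against 2 cannot give a p below 0.333.

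The levels of closely neighbouring models also differed by group. In 2656 pairs of models on the same strand within 1 kb, the model on the 3' side exceeded the one on the 5' side by a median log2 difference of 0.23 and 0.24 in the WT libraries. The difference was 0.02 and 0.06 in OE, and 1.19 and 1.22 in RNAi.

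**Figure D1:**
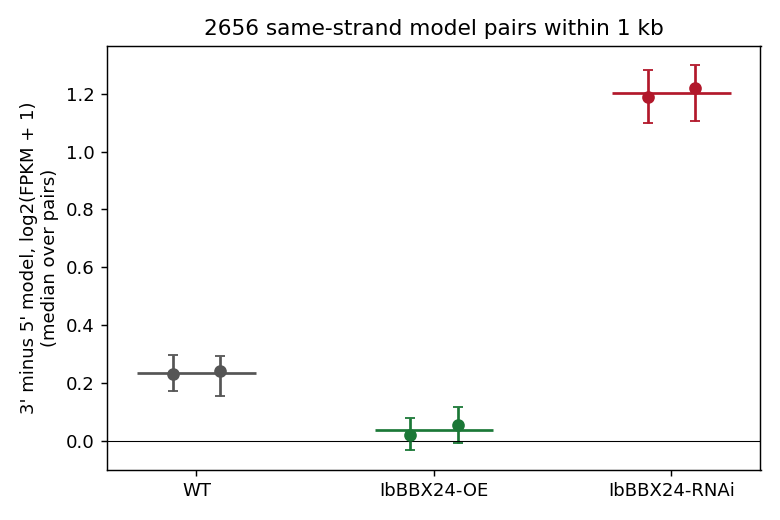
Median difference between the 3' and the 5' model of 2656 same-strand pairs within 1 kb, in log2(FPKM + 1), for each library. Points are libraries with 95% intervals of the median over pairs, and lines are group means; the RNAi libraries lie at 1.19 and 1.22, above the WT libraries at 0.23 and 0.24.

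In the overexpression leaves, 15407 of 50196 genes (30.7%) differed from WT, 6437 higher and 8970 lower. The split was 7072 higher and 8269 lower with trimmed mean scaling, and 7691 and 8116 after quantile normalization. It turned to 6497 and 5896 among annotated genes with the trend on model length removed. Of the 15407 genes, 1203 were at least 2-fold higher and 2239 at least 2-fold lower. Tai6.24109 rose from 0.691 ± 0.25 FPKM in WT to 122 ± 2.9 in OE (SD, n = 2 each), a log2 change of 6.20 (SE 0.10; limma adjusted p = 1.2e-07). This gene lies on scaffold 2356 at 50682 to 80653 on the minus strand, with 2 exons, and another model lies within 1 kb. Tai6.43892, with 2 exons on scaffold 9195 at 15859 to 16773, had 0 reads in WT and 54.6 ± 7.9 FPKM in OE, at least 541-fold higher (limma adjusted p = 1.5e-07). Tai6.45297, with 3 exons on scaffold 10636 at 1585 to 3771, fell from 110 ± 1.0 FPKM to 0.401 ± 0.11, a log2 change of −6.31 (SE 0.08; limma adjusted p = 5.1e-08). Tai6.21440, with 4 exons on scaffold 1959 at 87402 to 89386, fell from 54.2 ± 2.6 FPKM to 0.0960 ± 0.14. Its 2 reads in OE against 1237 in WT gave a ratio of 533 (147 to 4409), with a limma adjusted p of 1.4e-06. This gene was also lower in RNAi than in WT, with a log2 change of −5.54 (SE 0.17; limma adjusted p = 2.9e-07).

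Neighbouring genes moved together in this comparison. Of 2983 adjacent pairs with both members past the threshold, 71.1% changed in the same direction, against a mean of 50.7% and a highest value of 53.9% over 1000 shuffles of the calls. The one-sided permutation p was 0.0010, the smallest these shuffles can give (0.0015 adjusted over 3 comparisons). Here and in the other comparisons, the shuffles treat genes as exchangeable and hold the libraries fixed. Their p therefore does not cover variation between plants. Fold changes of adjacent models correlated at 0.47 in same-strand pairs within 1 kb. The correlation was 0.20 on opposite strands within 1 kb and 0.12 in same-strand pairs 5 to 20 kb apart. Close same-strand models may be parts of 1 transcript, and they were not left out of the 71.1%. In same-strand pairs within 1 kb, 161 had both members higher, 121 both lower, and 17 and 21 opposite directions. These counts, set against 2983 pairs, argue against such pairs as the whole source of the excess. Close models without a known strand are not among them.

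No list by gene structure passed camera's adjusted threshold in OE vs WT. Of the 5 lists, 1 had an unadjusted camera p under 0.05, and 2 had an unadjusted fry p under 0.05, which tests whether a list's genes move 1 way and not how they compare with others. Adjusted camera p-values ran from 0.16 for genes with 10 or more exons to 0.91 for single-exon genes. Among 2556 genes with 10 or more exons, 450 were higher and 332 lower (449 and 332 adjusted over the list alone). Of 12581 single-exon genes, 1543 were higher and 2168 lower (1525 and 2138 adjusted over the list alone). The 10% longest genes had 632 of 4125 higher and 554 lower (619 and 541 adjusted over the list alone), with a median log2 change of 0.02 and a mean of −0.00104. Among the 10% shortest, 521 of 4155 genes were higher and 546 lower (482 and 505 adjusted over the list alone). Of 8947 loci without a model, 886 were higher and 1945 lower (897 and 1964 adjusted over the list alone; camera adjusted p = 0.20).

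The count in OE vs WT rested on limma with 2 libraries per group, and 67.3% of genes had groups that did not overlap, against 33.3% by chance. It was 8719 without WT replicate 1, 9221 without WT replicate 2 and 10117 without OE replicate 2.

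**Figure D2:**
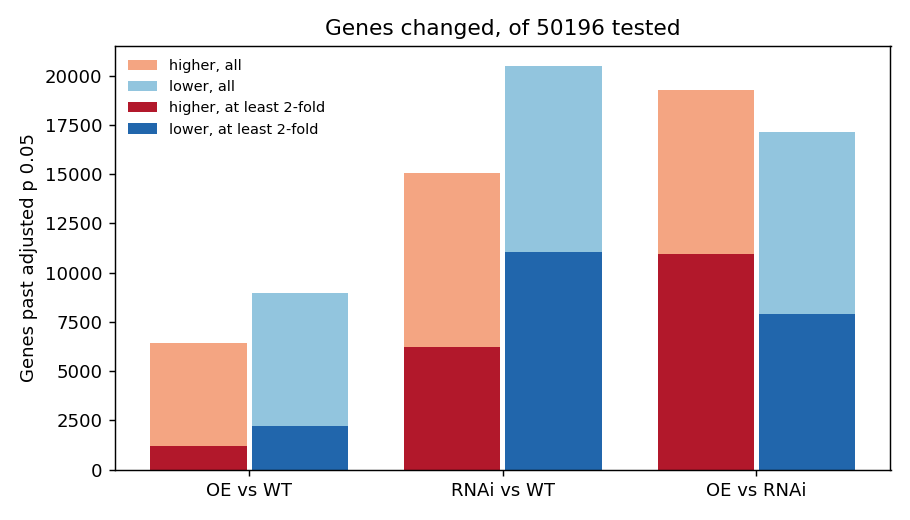
Number of genes past a limma adjusted p of 0.05 in each comparison, out of 50196 tested. Pale bars count all genes higher or lower and dark bars those changed at least 2-fold; RNAi vs WT had 15055 higher and 20491 lower, OE vs WT 6437 and 8970, and OE vs RNAi 19300 and 17148.

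In the RNAi leaves, 35546 genes (70.8%) differed from WT, 15055 higher and 20491 lower. This balance stayed with trimmed mean scaling of the libraries, at 15894 higher and 19764 lower. It turned to 17767 higher and 16755 lower after quantile normalization. It also turned, to 15407 and 14075, among annotated genes with the trend on model length removed. These last 2 corrections recentre each library, so they act on the split directly. Of the 35546 genes, 6218 were at least 2-fold higher and 11072 at least 2-fold lower. Tai6.24109 rose from 0.691 ± 0.25 FPKM in WT to 426 ± 16 in RNAi (SD, n = 2 each), a log2 change of 7.99 (SE 0.10; limma adjusted p = 1.7e-08). Tai6.43892 had 0 reads in WT and 111 ± 0.93 FPKM in RNAi, at least 1095-fold higher (limma adjusted p = 5.4e-08). Tai6.18788, a single-exon gene on the plus strand of scaffold 1577 at 31459 to 31959, had 235 ± 16 FPKM in WT and 0 reads in RNAi, at least 1344-fold lower (limma adjusted p = 1.0e-08). The locus Novel07594, with no coordinates in the annotation used here, had 87.4 ± 2.5 FPKM in WT and 0.0383 ± 0.054 in RNAi. Its 1 read in RNAi against 2537 in WT gave a ratio of 2325 (417 to 91886), with a limma adjusted p of 7.6e-08.

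**Figure D3:**
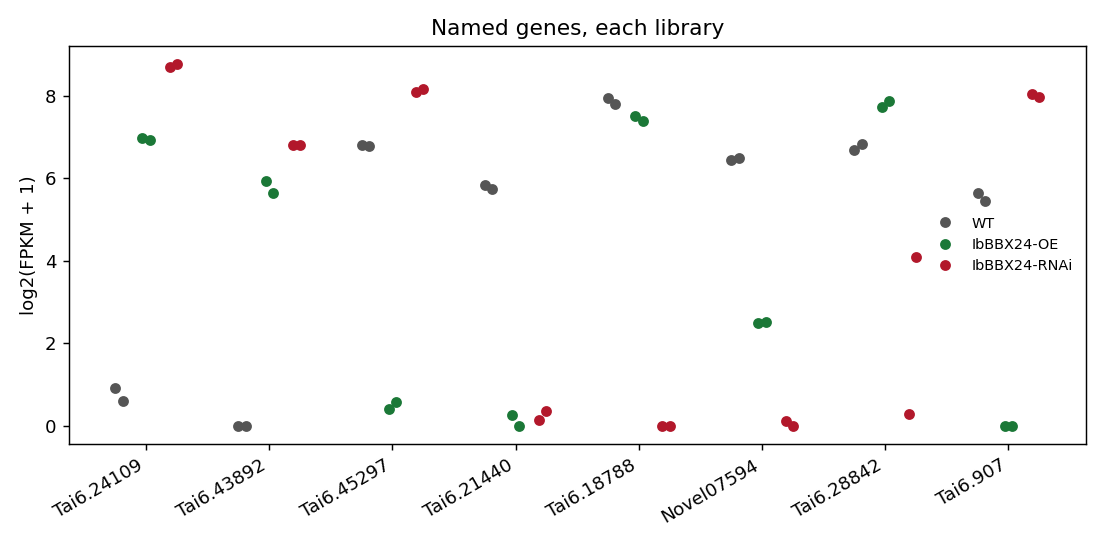
Level of each named gene in each library, as log2(FPKM + 1), with 1 point per library. Tai6.24109 and Tai6.43892 were higher in both transgenic lines than in WT, and Tai6.21440 and Novel07594 were lower in both. Tai6.28842 differed between the RNAi libraries, at 0.219 and 16.1 FPKM.

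Relative to other genes, lists of long and of many-exon genes were lower in RNAi than in WT and single-exon genes higher with camera's preset correlation. These calls were lost with an estimated correlation (adjusted p = 0.069 for the longest, 0.080 for many-exon and 0.069 for single-exon genes) and with the trend on model length removed (adjusted p = 0.93, 0.30 and 0.30). Of 2556 genes with 10 or more exons, 447 were higher and 1397 lower (448 and 1398 adjusted over the list alone), with a median log2 change of −0.40 against −0.14 for other genes. The camera adjusted p was 0.00091 with the preset correlation. Among the 10% longest genes, of 1993 bases or more, 625 of 4125 genes were higher and 2119 lower (617 and 2106 adjusted over the list alone; camera adjusted p = 0.0011). Of 12581 single-exon genes, 4828 were higher and 4374 lower (4843 and 4392 adjusted over the list alone), with a median of 0.04 against −0.21 for other genes. Their camera adjusted p was 0.024. The 10% shortest genes, of at most 374 bases, had 1207 of 4155 higher and 1690 lower (1206 and 1685 adjusted over the list alone; camera adjusted p = 0.93). Of 8947 loci without a model, 1816 were higher and 4065 lower (1789 and 4027 adjusted over the list alone; camera adjusted p = 0.076). In the same libraries, the 3' model of close same-strand pairs gained 0.99 log2 units over the 5' model in RNAi vs WT. The 95% interval of this median over pairs was 0.93 to 1.04. It treats pairs as independent, although some share a model, and does not cover variation between plants. With the trend on model length removed, the median difference from other annotated genes went from 0.21 to 0.16 for single-exon genes and from −0.32 to −0.15 for many-exon genes. For the 10% longest genes it went from −0.29 to 0.01. The interquartile range of single-exon genes ran from −0.83 to 0.89 before and from −0.72 to 0.99 after, that of many-exon genes from −0.997 to 0.099 and from −0.71 to 0.40, and that of the longest genes from −0.86 to 0.09 and from −0.46 to 0.48.

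**Figure D4:**
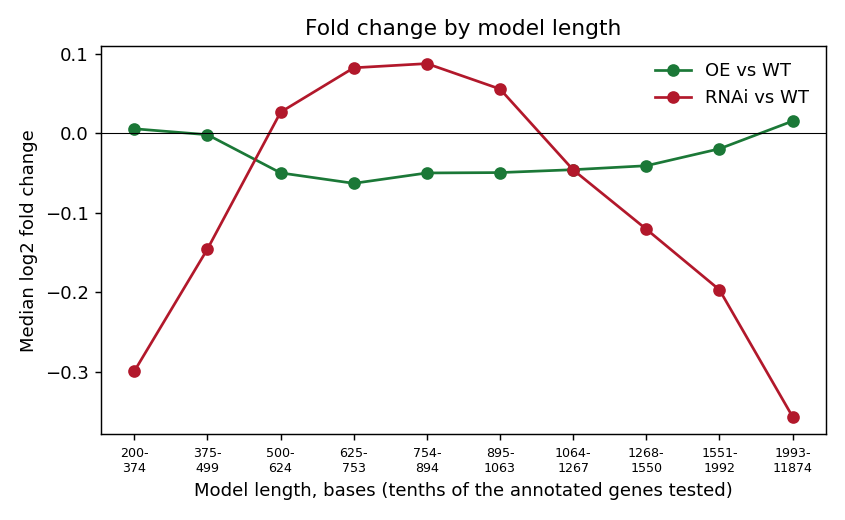
Median log2 fold change of annotated genes in 10 bins of model length, in bases, for OE vs WT and RNAi vs WT. The RNAi medians were −0.30 in the shortest bin and −0.36 in the longest and peaked at 0.09 in the fifth, while the OE medians stayed between −0.06 and 0.02.

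Of 13817 adjacent pairs with both members past the threshold in RNAi vs WT, 52.2% changed in the same direction. The shuffles gave a mean of 50.6% and a highest value of 51.9% (one-sided permutation p = 0.0010, the smallest possible; adjusted p = 0.0015). In the close same-strand pairs, 690 had a higher 3' and a lower 5' model, and 99 the reverse. Groups did not overlap for 86.3% of genes, against 33.3% by chance. Quantile normalization moved the median log2 change of all genes from −0.16 to 0.02, and the list tests above are relative to other genes. Among genes with no other model within 1 kb on the same or an unknown strand, 70.5% of 28664 passed when fitted alone.

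Between the transgenic lines, 36448 genes (72.6%) differed, 19300 higher in OE and 17148 lower. This balance too stayed with trimmed mean scaling, at 19052 higher and 17516 lower. It turned to 17128 higher and 18837 lower after quantile normalization. Among annotated genes with the trend on model length removed it turned to 14424 and 16107. Of the 36448 genes, 10944 were at least 2-fold higher in OE and 7902 at least 2-fold lower. Tai6.18788 had 175 ± 11 FPKM in OE and 0 reads in RNAi (SD, n = 2 each), at least 1004-fold higher in OE (limma adjusted p = 7.8e-09). Tai6.28842, a single-exon model without strand on scaffold 3247 at 42863 to 43949, had 222 ± 16 FPKM in OE and 8.18 ± 11 in RNAi. Its log2 change was 5.60 (SE 0.96; limma adjusted p = 0.00098), and the RNAi libraries held 0.219 and 16.1 FPKM. The change was 3.70 without RNAi replicate 1 and 7.51 without RNAi replicate 2. Tai6.907, a single-exon model without strand on scaffold 31 at 875 to 1371 with another model within 1 kb, had 0 reads in OE and 258 ± 8.8 FPKM in RNAi. It was at least 1378-fold lower in OE (limma adjusted p = 8.7e-09), and its WT level was 45.9 ± 4.8 FPKM. Tai6.45297 had 0.401 ± 0.11 FPKM in OE and 280 ± 9.5 in RNAi, a log2 change of −7.65 (SE 0.08; limma adjusted p = 7.8e-09).

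The many-exon, longest and single-exon lists passed in OE vs RNAi with the preset correlation. This comparison shares the RNAi libraries with RNAi vs WT, with the opposite sign, so its list results are not independent of those. Of 2556 genes with 10 or more exons, 1366 were higher in OE and 464 lower (1366 and 464 adjusted over the list alone; camera adjusted p = 0.00010, and adjusted p = 0.075 with an estimated correlation). The 10% longest genes had 2121 of 4125 higher and 725 lower (2111 and 713 adjusted over the list alone; camera adjusted p = 0.00026, and adjusted p = 0.053 with an estimated correlation). Of 12581 single-exon genes, 4247 were higher and 5302 lower (4267 and 5332 adjusted over the list alone; camera adjusted p = 0.043, and adjusted p = 0.053 with an estimated correlation). The single-exon call was lost without RNAi replicate 2 (adjusted p = 0.054). The 10% shortest genes had 1778 of 4155 higher and 1272 lower (1783 and 1272 adjusted over the list alone), and loci without a model had 3387 of 8947 higher and 2340 lower (3325 and 2277 adjusted over the list alone). Neither passed (camera adjusted p = 0.38). In close same-strand pairs the 3' model changed by −1.18 log2 units relative to the 5' model in OE vs RNAi. The 95% interval of the median over pairs was −1.25 to −1.12. With the length trend removed, the median difference from other annotated genes went from −0.26 to −0.21 for single-exon genes and from 0.38 to 0.17 for many-exon genes (adjusted p = 0.20 for both). For the 10% longest genes it went from 0.35 to 0.01 (adjusted p = 0.97). Of 14819 adjacent pairs with both members past the threshold, 51.1% changed in the same direction, against a mean of 50.1% and a highest value of 51.2% over 1000 shuffles (one-sided permutation p = 0.0030; adjusted p = 0.0030). The observed share lay within the range of the shuffles, close to its highest value. Groups did not overlap for 86.4% of genes, against 33.3% by chance.

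The comparisons of each line with WT were then set side by side. Of genes past the threshold in both, 2302 were higher in both lines and 4181 lower in both, while 2784 were higher in OE and lower in RNAi and 2511 the reverse. Independent lists of these sizes would share 1931, 3662, 2628 and 2690 genes in that order. Calls in the same direction made up 55.0% of the shared calls. They numbered 6483 against 5295 in opposite directions, 3985 against 2304 without WT replicate 1, and 4039 against 2565 without WT replicate 2. Calls in opposite directions were 3318 without OE replicate 1 and 3245 without OE replicate 2. Under a filter of a mean FPKM of at least 5, calls in the same direction were 4137 and calls in opposite directions 4551, so the balance turned. Because both comparisons used the same WT libraries, fold changes correlate with no effect at all. Across genes, which are not independent replicates, the observed correlation was 0.14, against a mean of 0.50 in 100 simulated data sets with no change. The observed covariance was 0.0833 and the simulated mean 0.0156, a difference of 0.0677. The 2 WT libraries cannot be split into parts of at least 2, so part of the excess may come from the shared controls.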

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

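The read-based test, the length correction, the omission of genes with a close model and the quantile-normalized overlap were chosen after seeing the data, and the other alternatives before. Named genes were picked as the largest fold changes past the threshold in these same data. That choice nearly fixed their direction and call under the alternatives, so these say little about other genes. All 144 values of the named genes under the alternatives run for them kept their direction and their call; none could be run for IbBBX24, which is not analysed here. The number of changed genes was 8719 to 14998 in OE vs WT, 30858 to 35358 in RNAi vs WT and 32780 to 35636 in OE vs RNAi over fits that left out 1 library, where the lone library is assumed to vary like the others. A fold of at least 2 left 3442, 17290 and 18846 genes in that order. Genes with no close model gave 8895, 20204 and 20885, from fewer genes tested (28664). A mean FPKM of at least 5 also tested fewer genes (27350) and gave 21648 in RNAi vs WT and 22286 in OE vs RNAi. The voom test on recovered reads called 17828, 36738 and 37042 genes.

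With an estimated correlation no list passed the adjusted threshold (unadjusted camera p under 0.05 for 0 of 5 in OE vs WT, 2 in RNAi vs WT and 3 in OE vs RNAi; unadjusted fry p for 2, 5 and 5). In RNAi vs WT the adjusted p was 0.069 for single-exon genes, 0.080 for 10 or more exons and 0.069 for the 10% longest genes, and in OE vs RNAi it was 0.053, 0.075 and 0.053. With the length trend removed, these were 0.30, 0.30 and 0.93, and 0.20, 0.20 and 0.97, with a median difference of the longest genes from others of 0.01 in both; the correction removes such a trend by construction. Leaving out 1 library gave 0.036 to 0.054 for single-exon genes in OE vs RNAi.

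Calls shared by OE vs WT and RNAi vs WT numbered 3985 to 5893 in the same direction and 2304 to 4829 in opposite directions with 1 library left out. The lowest of each came without WT replicate 1; without WT replicate 2 they were 4039 and 2565. Without OE replicate 1 or 2 the opposite calls were 3318 and 3245. Without genes that have a close model, 3673 calls went in the same direction and 3096 in opposite directions. At a mean FPKM of at least 5 the same-direction calls were 4137 and the covariance 0.0543; with a pseudocount of 0.1 the covariance was 0.244. The cause was not tested.

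Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.0099, −0.013 and 0.0099. With the replicate block the counts were 14743, 35315 and 36147, and no list or named gene changed its call.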

Other observations

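Chosen only after the result was seen were the tests of close pairs and of distant pairs, of multiplied RNAi values, of the reads expected for genes at 0 and of their neighbours, and of the WT noise. The most abundant genes were also looked at after the comparisons. Of the 10 genes with the highest mean FPKM over all 6 libraries, 10 were higher in RNAi than in WT. That mean includes the RNAi values, so the choice favours genes high in RNAi. The FPKM sums were also larger in RNAi, at 1067483 and 1074141, than in WT, at 984515 and 978030. With trimmed mean scaling 10 were still higher. After quantile normalization 2 were higher, 2 lower and 6 did not pass. That method gives the top ranks of every library the same values, so it removes much of such a difference by construction. In OE vs WT 1 of them was higher and 3 were lower, also with trimmed mean scaling. After quantile normalization 0 were higher and 3 lower.

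A set of 47 genes had 0 reads in both libraries of a group and at least 10 FPKM in both libraries of another, a list chosen after the values were seen. At 0 in RNAi and present in WT were 20 genes, and 13 showed the reverse. At 0 in OE and present in WT were 12 genes, and 6 showed the reverse. Between the lines, 9 genes were at 0 in RNAi and present in OE, and 13 showed the reverse. A pair of neighbouring genes on scaffold 923, at 68816 to 71264 and 78433 to 80657, reached 19.6 and 20.8 FPKM and 12.1 and 13.3 FPKM in the WT libraries and had 0 reads in the 4 libraries of both transgenic lines.

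In close same-strand pairs the 3' model gained on the 5' model in RNAi vs WT by a median of 0.99 log2 units. Pairs on opposite strands share no 3' side, so their difference was taken as right minus left along the scaffold. Their median of −0.01 (95% interval −0.08 to 0.07) would lie near 0 for that reason and is no control. The intervals given here are over pairs or runs of models, not over plants. A 3' gain from gene order at any distance is argued against by −0.20 (95% interval −0.27 to −0.15) in same-strand pairs 5 to 20 kb apart. Same-strand pairs 1 to 5 kb apart gave 0.10 (0.03 to 0.17). These values do not test an effect of order confined to close neighbours. A factor on a whole library largely cancels in the difference of close pairs, which was 0.80 and 1.13 with the RNAi values multiplied by 0.5 and 2. The value of 0.90 after quantile normalization (0.86 to 0.95) therefore does not test library-wide scaling. Uneven coverage of transcripts split over several models remains a candidate explanation; the steps along 266 runs of 3 models, the smaller 0.35 (0.17 to 0.54), are the same close pairs and add no separate test. RNA quality, library preparation and a change of transcript ends in the RNAi line coincide with the group and stay open. In the fit of all genes the share changed was 70.8% without and 74.6% with a close model, so close models alone do not account for the number of changed genes.

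For the genes at 0 the fewest reads expected were 90.5, but the minimum of 10 FPKM alone sets 64.5 for the shortest annotated model, so this is no separate test of too few reads. The loss of a stretch of DNA that spans neighbouring genes was met for few of them, since 15.4% of 26 loci, with neighbouring genes of the set and the groups counted once, had a neighbour also at 0 (exact 95% interval 4.36% to 34.9%; 22.6% of 31 when each gene and group counts, which are not independent). Uneven coverage cannot be told apart: 36.7% of 30 annotated genes had a close model (19.9% to 56.1%) against 30.5% of all annotated genes tested, and the genes are few. Loss or divergence of single genes and silencing in a line were not tested, and a difference between the genotypes also stays open.

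More shared calls went the same way than opposite ways in OE vs WT and RNAi vs WT. The covariance of 0.0833 was above the highest of 100 simulated values, 0.0166. This argues against independent noise of the WT libraries as the whole source of the covariance. The simulation held no deviation common to both WT libraries, so it does not test that. Nor does the covariance follow the call excess. At a mean FPKM of at least 5 the covariance was 0.0543, with 4137 calls in the same direction and 4551 in opposite directions. Library-wide scaling is argued against by a ratio of same to opposite calls of 1.24 after quantile normalization. The ratio was 1.19 without genes that have a close model, but this does not test uneven coverage. Genes with no close model can be unevenly covered too. In close same-strand pairs the 3' minus 5' difference was −0.18 in OE vs WT and 0.99 in RNAi vs WT. Leaving out genes with shifts of opposite sign cannot test an excess of calls in the same direction. The excess was absent at a mean FPKM of at least 5, where 47.6% of the shared calls went the same way. A response common to both transgenic lines, such as one to transformation, may contribute and was not tested, since no transformed control was analysed here.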
